A study of Homo sapiens with 4 samples.

How the data were processed

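RNA was sequenced from Sk-MES-1 cells, a line established from a human lung squamous cell carcinoma. The labels give 2 libraries of NR2F2 wild-type control cells and 2 libraries of cells in which NR2F2 had been knocked out with CRISPR. Total RNA was extracted from the cultures with a column kit for small samples, and indexed cDNA libraries were made with the Ovation SoLo RNA-seq system, per the labels' protocols. The titles of the knockout libraries also carry a code that the labels do not explain, which is not interpreted here. The labels do not say whether the replicates of a group came from separate cultures or clones, so p-values measure the spread between these libraries alone, which may be technical.

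The submitters' processing notes name STAR, Picard and HTSeq, without versions or the role of each, and the genome builds hg38 and GRCh38. The annotation release, the use of strand in the assignment of reads and the handling of duplicate reads are not given in the sources used here. The deposited values are scores: reads per gene that the authors scaled to about 20 M per library and rounded up to whole numbers, as the values themselves show. They are called scaled reads here. The table holds 58051 genes in 4 columns, and each column was tied to its library through the sample descriptions. The values are not divided by gene length, so levels of different genes are not compared. All cells are whole numbers except 2, both knockout values of SOX2, which hold 0.5.

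The columns sum to 20.0 M scaled reads each, which hides the depth. The pattern that scaling and rounding up leave among low values (values that never occur where 1 read is worth more than 1, values that occur too often where it is worth less) gave the worth of 1 read as 1.17 and 1.03 scaled reads in wild-type replicates 1 and 2, and 0.990 and 0.955 in knockout replicates 1 and 2. These correspond to 17.1, 19.5, 20.2 and 20.9 M reads on genes. A gene listed at 100 thus rested on roughly as many reads, and differences among genes listed below about 10 cannot be resolved at this depth. The recovery was not firm enough in every column for a test on whole reads to be used.

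The main test was set before the data were examined, as were the gene lists, the rule for the genes to be named and most alternatives. Values were transformed to log2(value + 10.0 scaled reads), a pseudocount of 0.5 CPM on the deposited totals, and genes with a mean of at least 20.0 scaled reads (1 CPM) over the 4 libraries were kept. The 2 groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend, 2-sided), and p was adjusted by the Benjamini-Hochberg method with a threshold of 0.05. No replicate block was used. Log2 changes are knockout minus wild type on this scale and understate the change of genes with low values. On simulated libraries with 15692 tested genes, the same steps recovered 85.9% of 64 genes changed 1.5-fold, 98.5% of 66 changed 2-fold and 100% of 64 changed 4-fold, and called 15 of 15498 unchanged genes. The simulated genes varied independently, with a common dispersion set by hand, few changed genes and no regional shifts. False calls under the broad differences seen in the data were therefore not tested.

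The 33 gene lists were tested as sets with limma's camera at a preset correlation of 0.01 between genes, 2-sided, where at least 5 members had been measured, with adjustment over these 31 lists. The camera test was repeated with an estimated correlation, and the fry rotation test served as another alternative. With an estimated correlation camera rests on the 2 residual degrees of freedom of the 4 libraries, so it could hardly pass any list here. In the list of NF-kB signalling and inflammatory cytokines the estimated correlation was -0.045, below the preset. Its camera p before adjustment still rose from 1.32e-07 to 0.0291. A call lost there does not show that correlated genes made it. On simulated libraries whose genes varied independently and without regional shifts, 5 of 5 raised lists were called and 0 of 25 others. False calls of lists with correlated genes were therefore not tested. In the data the estimated correlation was 0.73 in the interferon list, 0.98 in the mitochondrial list and 0.63 in the ribosomal list. For these lists the p at the preset overstates the evidence. Named genes are NR2F2, then the 10 highest and 10 lowest log2 changes among genes with adjusted p under 0.05, a mean of at least 100.1 scaled reads (5 CPM), a symbol that is not a clone name, and no overlap between the groups. In addition, up to 4 members with the largest changes are named in each list. Genes named outside this rule were chosen after their values were seen. Some genes that the rule takes are not reported here.

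Gene positions and types were taken from GENCODE release 29 on GRCh38, in which 57447 of the 58051 identifiers were found. To describe changes along the chromosomes, tested genes were taken in windows of 50 neighbours, and the genes were shuffled 100 times to obtain the largest deviation that a window reaches by chance. GC content and length came from the longest transcript of each gene, present for 99.3% of tested genes. The regional steps were run in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. They were chosen after the data were seen, as were 2 further alternatives: removal of the regional shift, and limma's voom weights on the reads worked back from the low values.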

Results

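Transcripts of 58051 genes were profiled in 4 Sk-MES-1 libraries, 2 of NR2F2 wild-type cells and 2 of NR2F2 knockout cells. NR2F2, also called COUP-TFII, is an orphan nuclear receptor that acts as a transcription factor. The study's title concerns its part in stemness, invasion and differentiation of tumours. Depth was 17.1 and 19.5 M reads on genes in the wild-type libraries and 20.2 and 20.9 M in the knockout libraries, and 31248 genes had a value above 0 in at least 1 library. Each library was counted as a separate sample, as the labels list them. The chi-square between their reads was 2.22 per gene in the wild type and 2.70 in the knockout, but 1.09 and 1.15 for genes with 20 to 99 reads, close to counting noise. Across genes, log2 values correlated at 0.997 within each group and at 0.943 between the first libraries of the groups. Genes are not independent replicates.

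The knockout was checked first at the targeted gene. NR2F2 (ENSG00000185551, chromosome 15, 96325938 to 96340263, plus strand) had 1387 and 1464 scaled reads in the wild-type libraries and 736 and 787 in the knockout libraries. The means were 1426 ± 54.4 (SD, n = 2) and 762 ± 36.1 (SD, n = 2), a log2 change of -0.90 (SE 0.0594, adjusted p = 3.31e-08), or 0.534 of the wild-type level. NR2F2 transcript was thus still present in the knockout libraries, and transcript levels do not show whether protein was made from it. Neighbouring genes on distal 15q also fell. With the running median of the 50 nearest genes taken off, the log2 change of NR2F2 was -0.14 (limma adjusted p = 0.0423). Those neighbours straddle a step in the shift, with medians of -0.13 for tested genes before it and -1.05 after it. The value of -0.14 thus depends on where the window falls, and its p ignores the error of the subtracted median.

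Other members of the NR2F list fell further than NR2F2 itself. NR2F1, the closest paralog, had 86 and 104 scaled reads in wild type and 2 and 2 in the knockout (log2 change -3.12, adjusted p = 1.83e-08), and NR2F1-AS1 fell by 3.34 on the log2 scale. NR2F2-AS1, which starts next to NR2F2, went from 68 and 59 to 10 and 12 (log2 change -1.81). Reads of a gene and its antisense partner cannot be told apart unless strand was used, which is not stated. NR2F6 did not pass, at 535 and 557 against 545 and 489 (adjusted p = 0.383). In all, 4 of 5 members fell and none rose (camera adjusted p = 0.00523, but adjusted p = 0.449 with an estimated correlation). The list holds the targeted gene and antisense genes of NR2F2 and NR2F1, so its call is partly set by the design.

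**Figure D1:**
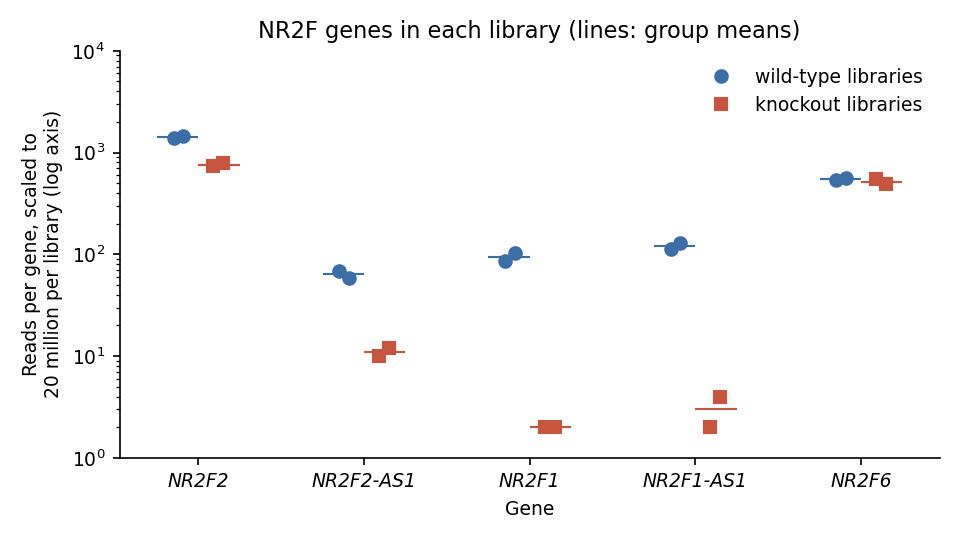
Scaled reads per gene on a log axis for the 5 genes of the NR2F list, with a circle for each wild-type library, a square for each knockout library and a line for each group mean. NR2F2 stood at 1387 and 1464 against 736 and 787, while NR2F1 stood at 86 and 104 against 2 and 2.

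Across the transcriptome the knockout libraries differed broadly from the wild type. Most measured members of the squamous differentiation, interferon and cholesterol synthesis lists were higher in the knockout, and most of the cytokine, immediate early and stress-response lists were lower. Of 31 lists tested with camera 13 passed, among them the NR2F list, which holds the targeted gene. With an estimated correlation 0 passed, but that version rests on 2 residual degrees of freedom and could hardly pass any list. Of 15795 tested genes, 5208 were higher and 4707 lower, together 62.8% (limma, adjusted p under the threshold of 0.05). Most of these changes were small: 702 genes were higher and 750 lower by at least 1 on the log2 scale, and 188 and 205 by at least 2. Among 12456 protein-coding genes tested, 4470 were higher and 3888 lower. With 1 library left out, the counts lay between 3186 and 3475 higher and between 3022 and 3490 lower. The lowest count on each side came without wild-type replicate 1, and the counts of higher genes without wild-type replicate 2 and without knockout replicate 1, at 3396 and 3375, were also more than 1.5 times below that from all libraries.

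The largest rises included an imprinted RNA, adhesion molecules, placental genes, a matrix protein and squamous keratins. H19, an imprinted long non-coding RNA, went from 15 and 13 to 4232 and 4145 scaled reads, 299-fold (log2 change 7.45, SE 0.0885, adjusted p = 3.30e-15). L1CAM, a cell adhesion molecule known from the nervous system and from invasive tumours, went from 41 and 44 to 8420 and 7664, 189-fold (log2 change 7.26). KRT13, a keratin of stratified epithelia that do not cornify, rose from 12 and 14 to 2477 and 2603 (log2 change 6.79), and KRT1, a keratin of suprabasal epidermis, from 0 and 4 to 575 and 665 (log2 change 5.73). KRT14, the keratin of basal cells, rose from 102 and 62 to 4400 and 4438, 53.9-fold (log2 change 5.62). ALPP, placental alkaline phosphatase, rose from 25 and 27 to 3945 and 3473 (log2 change 6.69), and PSG5, a pregnancy-specific glycoprotein, from 9 and 15 to 1630 and 1649 (log2 change 6.24). EDIL3, a matrix protein that binds integrins, rose from 4 and 6 to 1269 and 1281, and the adhesion molecule SDK1 from 5 and 11 to 957 and 841. MPPED2 was listed at 0 in both wild-type libraries and at 466 and 487 in the knockout. KRT14, ALPP and PSG5 have close paralogs, and reads shared with these make their values uncertain.

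The largest falls included genes that were near 0 in the knockout. PEG10 and SGCE, adjacent imprinted genes on chromosome 7 (94656325 to 94669695 and 94524204 to 94656572), went from 2156 and 2356 to 1 and 2 and from 385 and 376 to 0 and 1 (log2 changes -7.62 and -5.22). PPARGC1A, a coactivator that drives mitochondrial biogenesis, went from 1309 and 1214 to 1 and 1 (log2 change -6.85, SE 0.126, adjusted p = 2.43e-13). UGT8, an enzyme of galactolipid synthesis, had 517 and 525 scaled reads in wild type and was listed at 0 in the 2 knockout libraries. PRMT6, an arginine methyltransferase, went from 449 and 481 to 1 and 2, and PRAME, a tumour antigen with close paralogs, from 661 and 698 to 6 and 4. ANTXR2, CALB2 and ETV1 fell too (log2 changes -5.26, -4.91 and -4.79). ETV1, a transcription factor of the ETS family, kept 7 and 8 scaled reads of 479 and 472. No named gene changed direction under another pseudocount, filter or scaling.

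The gene lists follow, beginning with those on differentiation and stem cell identity. The fry test, which does not compare a list with other genes, called 23 lists, among them some given here as not passed, but neither the mitochondrial nor the ribosomal list. The counts of members did not differ when p was adjusted over the list alone, except where a second count is given. Of 24 measured members of the squamous differentiation list, 16 rose, 3 fell and 5 did not pass, with a median log2 change of 0.89 (camera adjusted p = 0.000882, adjusted p = 0.50 with an estimated correlation). Besides KRT13 and KRT1, KRT4 and KRT16 rose, by log2 changes of 4.50 and 4.01. The list of basal and squamous stem cell genes split, with 10 higher, 10 lower and 2 not passed of 22 (camera adjusted p = 0.852). Its median was -0.03 and its mean 0.33. KRT14, PDPN (log2 change 3.40) and KRT15 (2.83) rose, and NGFR, a receptor found on basal cells, fell by 2.77. SOX2, a transcription factor of squamous tumours, was below the filter and not tested. It was listed at 29 and 27 in wild type, and both knockout values are 0.5, the only entries of the table that are not whole numbers.

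The mesenchymal and EMT list also split, with 6 higher, 8 lower and 3 not passed of 17 (camera adjusted p = 0.852). COL5A1, a fibrillar collagen chain, rose (log2 change 4.89) and so did the actin-binding protein TAGLN (2.62), while the intermediate filament vimentin, VIM, and the transcription factor TWIST1 fell (log2 changes -3.36 and -2.04). The list's median was -0.02 and its mean 0.01, and the fry test gave the opposite direction to camera (higher, adjusted p = 0.0281). In the list of epithelial junction and identity genes, 11 of 31 members were higher and 14 lower, or 12 and 14 adjusted over the list alone (camera adjusted p = 0.728). CLDN1, a tight junction claudin, rose (log2 change 4.21), as did the desmosomal plaque protein DSP (1.31). The epithelial transcription factors ELF3 and EHF fell (-1.26 and -0.90).

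Invasion and matrix remodelling genes were mostly lower, with 16 of 26 measured members lower, 6 higher and 4 not passed (median log2 change -0.47, camera adjusted p = 0.00731, adjusted p = 0.479 with an estimated correlation). ADAM19, a membrane metalloproteinase, fell by 4.51 on the log2 scale, and so did the plasminogen activators PLAT and PLAU (-1.72 and -1.53). MMP13, a collagenase, rose (log2 change 2.82). Of 14 angiogenic and vascular factors, 6 were higher and 8 lower, and the list did not pass (camera adjusted p = 0.177). ANGPTL4, PGF, VEGFC and the co-receptor NRP1 fell (log2 changes -2.61, -2.57, -2.40 and -2.33).

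Interferon and antigen presentation genes rose together. Of 36 measured genes of the type I interferon response, 31 rose, 1 fell and 4 did not pass, or 33 and 1 adjusted over the list alone, with a median log2 change of 1.13 (camera adjusted p = 1.12e-09). The call was lost with an estimated correlation (camera adjusted p = 0.635). That correlation was 0.73, so these genes moved largely together and the p at the preset of 0.01 overstates the evidence. The antiviral genes MX2, RSAD2, IFI44L and CMPK2 rose by log2 changes of 3.49, 3.17, 2.95 and 2.73. The knockout libraries stood apart in this list, with 35 of 36 members higher in replicate 2 than in replicate 1 (median difference 0.37 on the log2 scale). MX2 had 16 and 21 scaled reads in wild type and 214 and 444 in the knockout, and IFI44L had 51 and 41 against 252 and 704. Without knockout replicate 2 the list still passed (camera adjusted p = 3.07e-07), as did MX2 and IFI44L, at log2 changes of 2.98 and 2.23. IFI44L no longer passed without wild-type replicate 2 (adjusted p = 0.0562). Of 15 antigen presentation genes, 10 rose and none fell (camera adjusted p = 0.00629, adjusted p = 0.449 with an estimated correlation). They were led by HLA-DMA (log2 change 1.07), HLA-F (0.87), HLA-C (0.54) and HLA-E (0.52). Reads can be shared among HLA-F, HLA-C and HLA-E.

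Genes of NF-kB signalling and inflammatory cytokines went the other way, with 16 of 19 lower, 2 higher and 1 not passed (median log2 change -1.34, camera adjusted p = 1.36e-06, adjusted p = 0.405 with an estimated correlation). IL1B and IL1A, the interleukin-1 genes, fell (log2 changes -3.61 and -2.80), as did PTGS2, which makes prostaglandins (-2.29). The chemokine CCL5, which interferon also induces, rose (log2 change 3.17). Immediate early genes were lower too, with 15 of 23 lower and 4 higher, or 15 and 5 adjusted over the list alone (median -0.77, camera adjusted p = 0.000297, adjusted p = 0.405 with an estimated correlation). SPRY4, DUSP4 and DUSP6, feedback inhibitors of MAP kinase signalling, and FOSL1, an AP-1 subunit, fell (log2 changes -3.04, -2.84, -2.55 and -1.87).

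Cholesterol synthesis genes rose as a group, 21 of 24 higher, 1 lower and 2 not passed, with a median log2 change of 0.89 (camera adjusted p = 1.12e-09, adjusted p = 0.405 with an estimated correlation). LSS, HMGCS1 and MVD, enzymes of the pathway, rose by log2 changes of 2.11, 1.87 and 1.33. The list of fatty acid and lipid genes missed the threshold with 15 of 23 higher and 5 lower (camera adjusted p = 0.0531), but passed without a filter (adjusted p = 0.00474), with the filter at 5 CPM (0.0343) and with the regional shift removed (0.0138). PLIN2, a lipid droplet coat protein, and the elongase ELOVL6 fell (-1.62 and -1.44), and PPARA and CPT1A, which serve fatty acid oxidation, rose by log2 changes of 0.74 and 0.69. PPARA had a log2 change of 0.04 and no longer passed once the regional shift was removed (adjusted p = 0.652).

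Stress-response genes were lower in the knockout. In the list for the integrated stress and unfolded protein response, 18 of 26 members were lower and 6 higher, or 19 and 6 adjusted over the list alone (median -0.50, camera adjusted p = 3.18e-05, adjusted p = 0.405 with an estimated correlation). STC2, a secreted stanniocalcin, the glutathione-degrading CHAC1, DDIT4 and the serine synthesis enzyme PSPH fell (log2 changes -3.86, -2.74, -2.08 and -1.98). Of 29 hypoxia and glycolysis genes, 17 fell and 5 rose, or 18 and 5 adjusted over the list alone (median -0.14, camera adjusted p = 0.00363, adjusted p = 0.449 with an estimated correlation). CA9, ANGPTL4, BNIP3 and DDIT4, all known to be induced by hypoxia, fell the most (log2 changes -2.78, -2.61, -2.24 and -2.08). Heat shock genes were lower in 10 of 14 cases and higher in 2 (median -0.15, camera adjusted p = 0.0118, adjusted p = 0.50 with an estimated correlation). The chaperone genes HSP90AA1, HSPD1 and HSPE1 fell (log2 changes -0.62, -0.60 and -0.58), as did DNAJB4. HSPD1 and HSPE1 no longer passed once the regional shift had been removed (adjusted p = 0.351 and 0.984). The list was also lost with that removal (adjusted p = 0.134).

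All 13 mitochondrially encoded genes were lower, with a median log2 change of -0.35 (camera adjusted p = 0.000604, adjusted p = 0.635 with an estimated correlation). The estimated correlation was 0.98, so these genes moved almost as 1, and the p at the preset of 0.01 overstates the evidence. MT-CYB, MT-ND4L, MT-ND4 and MT-CO2 fell the most (log2 changes -0.64, -0.53, -0.51 and -0.43). All genes with a symbol that starts with MT-, not only the 13 of the list, took 2.49 and 2.12% of the total in the wild-type libraries. In the knockout libraries they took 1.86 and 1.78%. MT-CO2 did not pass without a filter (adjusted p = 0.0564), MT-ND4 and MT-CO2 did not without knockout replicate 1 (adjusted p = 0.0518 and 0.0636), and the 4 named genes did not pass without knockout replicate 2 (adjusted p from 0.0514 to 0.0858). Ribosomal protein genes were higher in 27 of 39 cases and lower in 4 (median 0.14, camera adjusted p = 0.0108, adjusted p = 0.833 with an estimated correlation). Their estimated correlation was 0.63, so the p at the preset overstates the evidence here too. The call was lost without wild-type replicate 2 (adjusted p = 0.0909) and after removal of the regional shift (adjusted p = 0.256). RPL18, RPS28 and RPS19 rose by log2 changes of 0.51, 0.49 and 0.46 and RPL5 fell by 0.57, but once the regional shift was removed RPS19 and RPL5 changed sign and RPL18 no longer passed (log2 change 0.09, adjusted p = 0.159). RPS28 no longer passed without a filter (adjusted p = 0.0754) or without wild-type replicate 1 or knockout replicate 1 (adjusted p = 0.0943 and 0.0774).

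**Figure D2:**
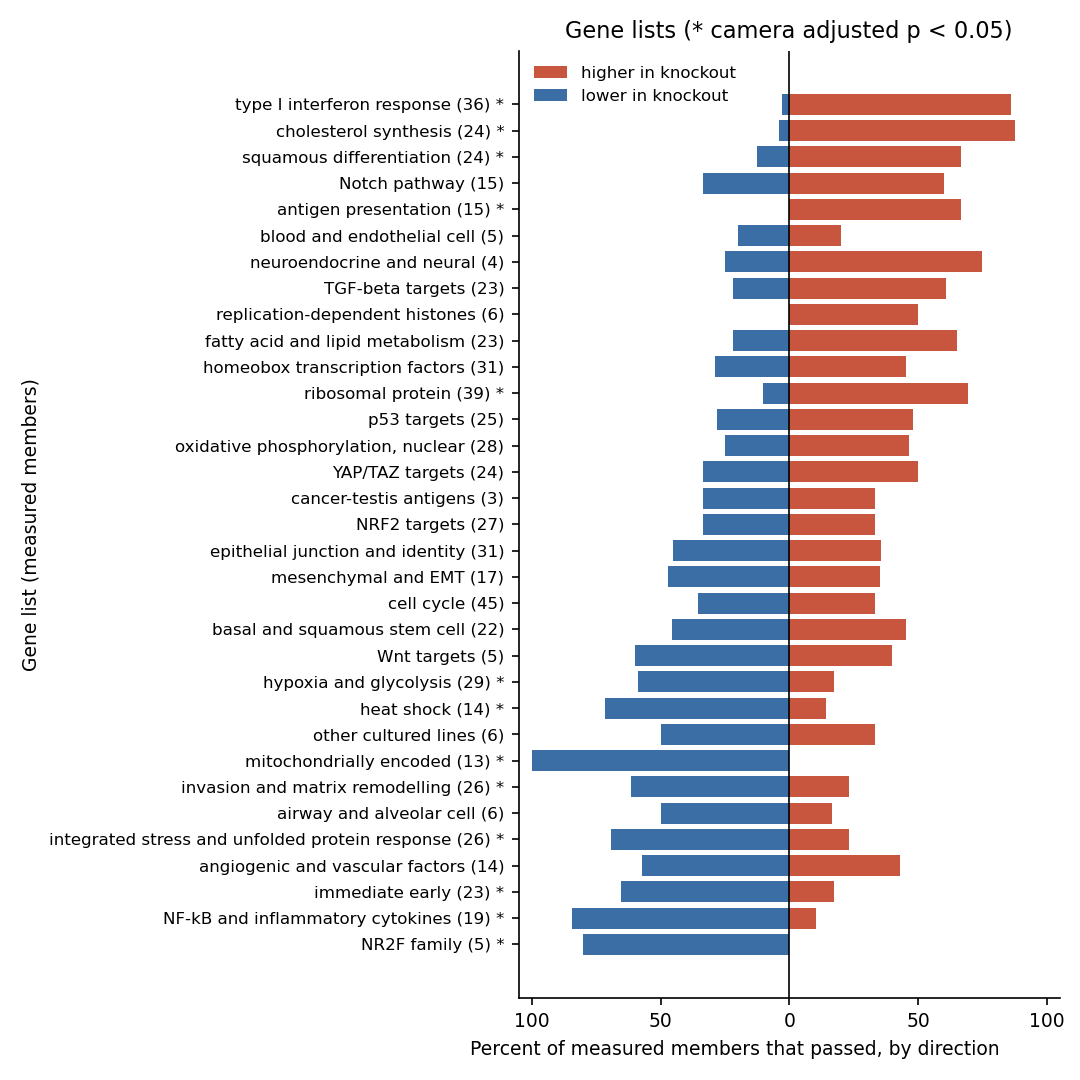
Percent of measured members of each of the 33 gene lists that were higher (right, red) or lower (left, blue) in the knockout, ordered by the median log2 change, with the number of measured members in brackets and a star for the 13 lists with a camera adjusted p under 0.05. Interferon, cholesterol and squamous differentiation genes lie at the top, and the NR2F and cytokine lists at the bottom.

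The Notch, TGF-beta, YAP/TAZ, Wnt and NRF2 lists did not pass with camera. Among 15 Notch pathway genes, 9 were higher and 5 lower (camera adjusted p = 0.124), but the list passed with the filter at a mean of 5 CPM (adjusted p = 0.0173). The list members HES2 and HES4 and the glycosyltransferase LFNG rose by log2 changes of 3.50, 1.98 and 2.41, and HEY1 fell by 2.73. Of 23 TGF-beta target genes, 14 were higher and 5 lower (camera adjusted p = 0.124), with SMAD6 and ID2 up by 2.84 and 2.66 and LTBP3 and CTGF down (log2 changes -2.44 and -2.18). YAP/TAZ target genes had a median of 0.09 and a mean of -0.16, with 12 of 24 higher and 8 lower (camera adjusted p = 0.965). NT5E, CTGF and ASAP1 fell (-3.18, -2.18 and -1.48), and IGFBP3 rose (log2 change 2.13). Of 5 measured Wnt targets, 2 were higher and 3 lower (camera adjusted p = 0.975; TCF7 -0.98, DKK1 0.98, ZNRF3 0.62, RNF43 -0.38). The list's median was -0.12 and its mean 0.03. Of 27 NRF2 targets, 9 were higher and 9 lower (camera adjusted p = 0.754), with AKR1C1, SLC7A11, AKR1C3 and GCLM down by log2 changes of -2.11, -1.85, -1.78 and -1.52. AKR1C genes are close paralogs.

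Proliferation genes changed by small amounts and in both directions. Of 45 cell cycle genes, 15 were higher and 16 lower, none by as much as 1 on the log2 scale (camera adjusted p = 0.528). Of all tested genes 62.8% passed. The fry test called the list lower (adjusted p = 0.0149). KIF20A rose (log2 change 0.87), and MCM6, CCNE2 and BUB1B fell (-0.83, -0.67 and -0.65). CCNE2 no longer passed once the regional shift was removed (adjusted p = 0.646). Of 25 p53 target genes, 12 were higher and 7 lower, or 12 and 8 adjusted over the list alone (camera adjusted p = 0.741). GDF15 and FAS fell (-1.40 and -1.23), and TP53INP1 and the cell cycle inhibitor CDKN1A rose by log2 changes of 1.23 and 0.99. Nuclear genes of oxidative phosphorylation were higher in 13 of 28 cases and lower in 7 (camera adjusted p = 0.528), with UQCRB, CYC1 and COX6C lower (-0.64, -0.50 and -0.44) and COX5B higher (0.49). UQCRB no longer passed after removal of the regional shift, COX6C then changed sign, and COX5B did not pass without wild-type replicate 1 (adjusted p = 0.0573). Of 6 measured replication-dependent histone genes, 3 were higher and none lower, or 2 adjusted over the list alone (camera adjusted p = 0.410). HIST1H2BD, HIST1H1C and HIST1H2BK had log2 changes of 0.87, 0.63 and 0.31, and HIST1H2BC one of 0.35 that did not pass. HIST1H2BK lost its call or changed sign in most alternatives, HIST1H2BD did not pass without knockout replicate 1 (adjusted p = 0.0528), and HIST1H1C did not with the regional shift removed (log2 change 0.19, adjusted p = 0.256). Of 31 homeobox and related transcription factors, 14 were higher and 9 lower, or 14 and 10 adjusted over the list alone (camera adjusted p = 0.338), led by DLX3 (2.40), HOXA13 (1.75), HOXC13 (1.55) and MSX2 (1.47).

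Markers of other cells were sparse. Of 23 airway and alveolar markers, 6 were measured, of which 1 was higher and 3 lower, or 1 and 4 adjusted over the list alone (camera adjusted p = 0.232). FOXA2, FOXA1 and AGER fell (-2.92, -1.10 and -0.66), and DNAH5 had a log2 change of -0.32 that did not pass. Of 20 blood and endothelial markers, 5 were measured, with CSF1R higher (0.87), CD68 lower (-0.69), and CDH5 (0.44) and VWF (0.39) not passed (camera adjusted p = 0.917). Only 4 neuroendocrine and neural genes were measured, of which NEFL (4.62), NEFM (0.52) and ENO2 (0.26) rose and TUBB3 fell by 0.40. Among markers of other cultured lines, 6 of 20 were measured (camera adjusted p = 0.456), 2 of them higher and 3 lower. VIL1 fell by 0.50, and ESR1 and PAX8 rose by log2 changes of 1.15 and 0.56. PAX8 did not pass when any 1 library was left out, ENO2 when any but wild-type replicate 1 was, NEFM without either knockout library, and AGER without the second library of either group (adjusted p from 0.0512 to 0.0801). With the regional shift removed, VIL1, PAX8 and ENO2 did not pass (adjusted p = 0.526, 0.270 and 0.0762). DNAH5 passed with quantile normalization, without the trend and with the regional shift removed (adjusted p = 0.0493, 0.0402 and 0.0379), and CDH5 passed without wild-type replicate 2 (log2 change 0.76, adjusted p = 0.0417). Of 21 cancer-testis antigens, 3 were measured: SPANXB1 fell by 3.72, CTAG2 rose (log2 change 3.26), and MAGEA4 had a log2 change of 0.03 that did not pass. SPANXB1 and CTAG2 have near-identical copies.

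The size and sign of changes followed position along the chromosomes, a description chosen after the data were seen. Of 302 windows of 50 neighbouring tested genes, 53 had a median log2 change farther from the overall median than the largest deviation (0.39) in 100 shuffles of the genes, 38 of them lower and 15 higher. On chromosome 1 from 88852932 to 145859836, 171 of 200 genes were lower and 10 higher, with a median log2 change of -0.78. On chromosome 8 from 73008864 to 140635619, 158 of 200 were lower (median -0.55), and on chromosome 2 from 135985176 to 200864744, 150 of 200 (median -0.56). On chromosome 22 from 30240447 to 50532580, 196 of 250 genes were higher and 27 lower (median 0.62), and on chromosome 6 from 291630 to 29749049, 116 of 150 were higher and 2 lower (median 0.51). The windows were chosen by the changes of these same genes, so counts within them describe the shift and are no separate test. In the 53 windows 80.7% of genes were called, against 59.0% of genes in the others, a difference that follows in part from that choice.

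**Figure D3:**
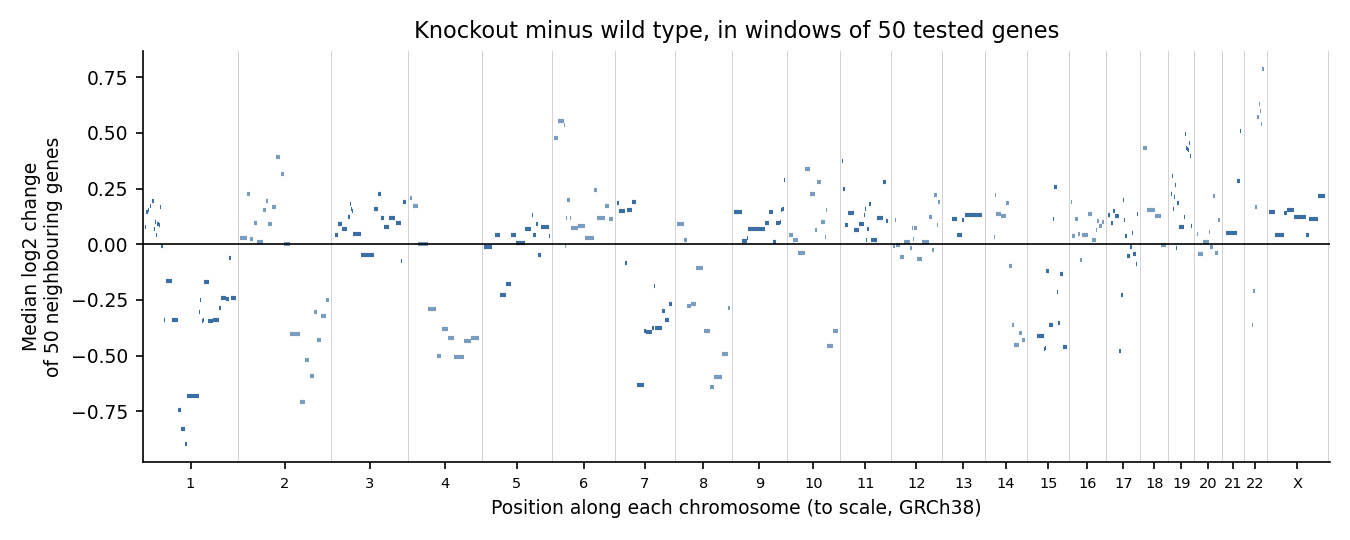
Median log2 change (knockout minus wild type) of each window of 50 neighbouring tested genes, drawn over its span along chromosomes 1 to 22 and X, in alternating shades. Window medians ran from -0.90 on chromosome 1 to 0.78 on chromosome 22.

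NR2F2 lies in one such stretch. Of 27 tested genes between NR2F2 and the end of the long arm of chromosome 15 (98648539 to 101976543), 26 were lower in the knockout and 1 did not pass, with a median log2 change of -1.16. They include IGF1R, the insulin-like growth factor receptor (log2 change -0.58), the transcription factor MEF2A (-1.29) and ALDH1A3, an enzyme of retinoic acid synthesis (-1.62), named after their values were seen. The 50 tested genes before NR2F2, leaving out NR2F2-AS1, had a median of -0.15, and 22 of them were lower, but the nearest 10 of them had a median of -0.39.

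**Figure D4:**
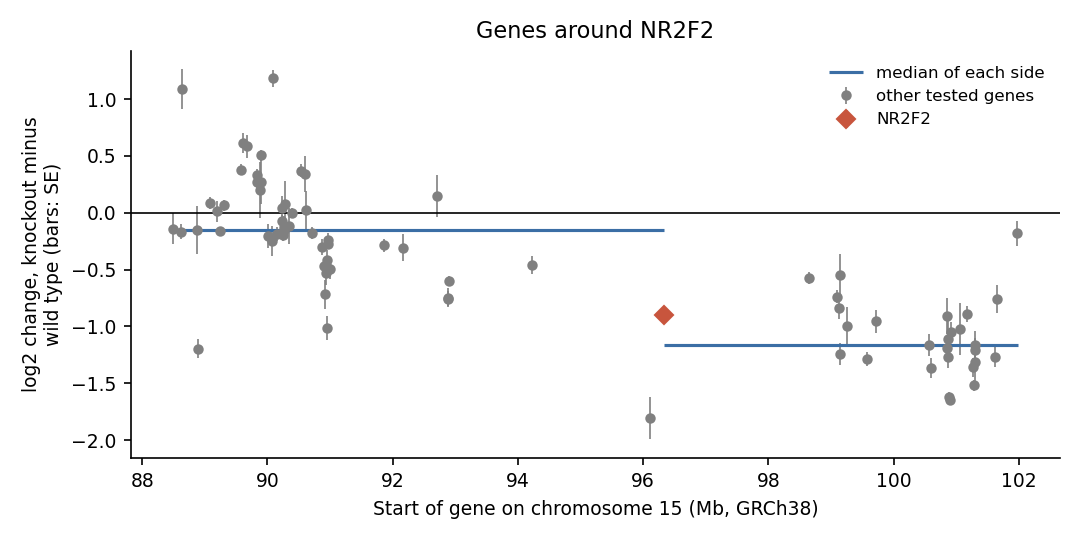
Log2 change with its standard error for each tested gene on chromosome 15 from 88.5 Mb to the end, by start position, with NR2F2 as a diamond and lines for the medians of the 50 genes before it and the 27 after it. The median was -0.15 before NR2F2 and -1.16 after it. NR2F2-AS1, the lowest point beside NR2F2, is in neither median.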

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

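NR2F2 was lower in the knockout at an adjusted p under 0.05 in each alternative that kept all libraries. Its log2 changes ran from -0.94 to -0.85 when 1 library was left out. With the regional shift removed the change was only -0.14, a value that depends on where the window of neighbours falls. NR2F2 misses a minimum log2 change of 1 (-0.90), a limit that leaves 702 higher and 750 lower genes by its construction. The extremes of higher (3186 to 3475) and lower genes (3022 to 3490) with 1 library left out come from fits with fewer samples, in which the lone library is assumed to vary like the other group. Without a filter, 4032 genes were higher and 4351 lower, of which 3594 and 3445 were also called with the filter. Quantile normalization gave 5060 and 4808. Of the gene lists, 13 passed in the main test and 23 with fry, which tests a list alone rather than against other genes. With an estimated correlation 0 passed, a version that rests on 2 residual degrees of freedom and could hardly pass any list. The mesenchymal and EMT list was higher with fry (adjusted p = 0.0281). With the replicate block, 5064 genes were higher, 4570 lower and 14 lists called, with the fatty acid and lipid list added (adjusted p = 0.0450). Same-numbered libraries did not deviate together (correlation -0.09), so the number is not shown to pair them. Among alternatives chosen after the data were seen, removal of the regional shift gave 4194 higher and 4342 lower genes, of which 3427 and 3256 were also called in the main test and 294 in the opposite direction. Of the 13 lists 11 stayed, and the fatty acid and lipid list was added. It gave log2 changes of 0.20 for RPL5, -0.10 for RPS19, 0.19 for COX6C, -0.26 for HIST1H2BK and -0.25 for MAGEA4, since neighbours' shifts were subtracted. Weights from voom gave 5205 and 4695. The planned tests on whole reads were not run because whole reads could not be recovered firmly. Depth limits genes below about 20 scaled reads, which were not tested.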

Other observations

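All tests in this part were chosen after the data were seen, and the genes named here were picked after their values were seen. EGFR fell from 35028 and 36115 scaled reads to 5931 and 6155 (log2 change -2.56), and of 7 ligand genes EREG, HBEGF, AREG and TGFA fell as well (log2 changes -2.92, -2.61, -2.38 and -0.76). BTC did not pass (log2 change -0.21), and EGF and EPGN were below the filter. The related receptors ERBB2 and ERBB3 rose by log2 changes of 0.50 and 0.54, while MET fell by 0.52. Among keratins outside the rule for named genes, KRT17 rose from 227 and 224 to 5652 and 5447, although it can share reads with KRT14 and KRT16, and KRT5 from 16390 and 16809 to 33516 and 32241. TP63, the transcription factor of basal cells, fell by 0.38.

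Neighbours of some strongly raised genes were higher too, and no cluster was tested as a set. On chromosome 11, H19 was accompanied by SYT8 (log2 change 4.01), LSP1 (3.48), TNNT3 (3.17), TNNI2 (3.10) and CTSD (1.08). By contrast, MRPL23 and PHLDA2 did not pass (0.14 and -0.09), DUSP8 stayed at 4 scaled reads or fewer and IGF2 stayed at 3 scaled reads or fewer. On chromosome 19, the zinc finger genes ZNF254, ZNF85, ZNF100 and ZNF91 rose by log2 changes of 4.45, 2.68, 2.50 and 1.85, while ZNF43, ZNF208 and ZNF257 had at most 1 scaled read in any library. The pregnancy-specific glycoprotein genes PSG9 and PSG4 rose by log2 changes of 2.32 and 2.10, with reads that can be shared among their paralogs. Among other placental genes, ALPPL2, near ALPP on chromosome 2, rose from 2 and 0 to 522 and 423 (log2 change 5.45). In contrast, CGA, CSH1 and CSH2 were listed at 0 in all libraries. Imprinted genes went both ways: PLAGL1 went from 47 and 49 to 0 and 1, MEST fell by 0.47, and KCNQ1OT1 and GNAS rose by log2 changes of 0.97 and 0.70.

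For the regional shifts, GC content, transcript length and level together accounted for 1.98% of the variance of single-gene log2 changes, with extreme changes capped. This share does not show how far they shift window medians. After a fit on them 41 of the 53 shifted windows (77.4%) were still past the limit, which argues against such a bias as the whole cause. The bound on windows kept was first 80%, which would have left this undecided, and was lowered to 50% after the value was seen. In 13 windows chosen by the genes at odd places, a median of 92.0% of the genes at even places lay on the same side, against 64.0% in the other windows, as a difference in chromosome copy number between the cultures would give. Broad chromatin changes could do the same, and DNA was not analysed here. For distal 15q, loss of the chromosome end beyond the edited NR2F2 locus may be considered, and the largest step was placed at -4 tested genes from NR2F2 (bootstrap interval -6 to -1), at 92.9 Mb. The interval leaves out NR2F2 itself, but with so few genes in between, a break there cannot be told apart from a break elsewhere. Chromosome 15 was also lower from 20.4 to 44.5 Mb and from 51.9 to 63.1 Mb (medians -0.46 and -0.36). Loss of the chromosome end would not cover these stretches.

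In all, 12 genes with at least 100 scaled reads in both wild-type libraries had 3 or fewer in both knockout libraries, among them CCND2, SPRY1, BMPR1B and MMP16, and 13 did the reverse, among them ANOS1, PRKAA2 and CADM1. For the 12 lost in the knockout, deletions that take the neighbours to near 0 as well are argued against as the general cause. The 22 neighbours had a median log2 change of -0.34, with PEG10 and SGCE counted among them and a gene without a position left out. Both neighbours of UGT8 fell, however (ARSJ -1.56, TRAM1L1 -1.20). UGT8, SPRY1, BMPR1B, MMP16, PKIA, PRMT6, PEG10 and SGCE lie in stretches that were lower in the knockout, while PPARGC1A and CCND2 do not. A lower copy number around the genes in those stretches is therefore not excluded. The 13 others, some with neighbours that rose too (TNNI2 and TNNT3 beside LSP1), were not tested. PEG10 and SGCE are each other's neighbours, and with CASD1 (-0.27) and PON3 (-0.33) on either side a deletion limited to this pair stays open. Libraries of another cell line behind one label cannot be told apart from an effect of the knockout: 0 of 8 genes that many people lack were on in one group and off in the other, and 4 were on in every library, but this excludes no mix-up. The labels carry 1 knockout name for both libraries, so differences between clones that do not come from NR2F2 likewise cannot be told apart from its loss.

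Lower ERK signalling is a candidate explanation for the fall of MAP kinase feedback genes. Of 10 genes used as a read-out of ERK output, 7 were lower and 1 higher, with a median log2 change of -1.58, but most had already been seen to fall when the list was written, so this is no test. The list includes ETV5, ETV4 and PHLDA1 (log2 changes -1.66, -1.73 and -1.51), but EPHA4 rose from 30 and 23 to 825 and 924. The regional shifts do not account for the fall, since the median was -1.52 after their removal. Lower ERK signalling cannot be told apart from a direct effect of NR2F2 on these genes. Nor can either be told apart from clone differences that do not come from NR2F2, or from another cell line behind one label.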
